A study of Caenorhabditis elegans with 4 samples.

How the data were processed

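MRE-11 occupancy was measured by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in Caenorhabditis elegans hermaphrodites of the strain fem-2(b245), at the young adult stage in which the germline is present. MRE-11 is the nuclease of the MRE-11 and RAD-50 complex, which acts in the formation and repair of DNA double-strand breaks, including those of meiosis. The fem genes are needed for male development and for spermatogenesis. Per the series' design text the worms were kept at 20 degrees Celsius. Per the labels' protocols, frozen worms were ground and crosslinked with EGS and then with EGS plus formaldehyde, sheared by sonication, and precipitated with an affinity-purified polyclonal rabbit antibody raised against part of MRE-11. The series holds 2 ChIP libraries and 2 input libraries, with replicate numbers given in the titles.

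Reads were aligned with BWA to ce10, per the submitters' processing notes. The version and settings of the aligner are not given in the sources used here. Coordinates are those of genome build WormBase WS220, per the file headers. There are 3 peak lists: 1 for each ChIP replicate, made with MACS per the source column of the files, and 1 for the whole series, made with MACS v2 per its source column. The control, the thresholds and the handling of duplicate reads are not given in the sources used here, nor is whether the whole-series list was called on pooled reads. Each peak carries a score that the authors' caller wrote, and the scale of the deposited score is not stated in the files. The lowest scores were 50.12 in replicate 1, 50.01 in replicate 2 and 1.30 in the whole-series list. Scores were used only to rank peaks within a list. Many peaks shared 1 high value, which limits the ranking at the top: 280 replicate 1 peaks and 300 replicate 2 peaks had a score of 3100, and 172 whole-series peaks had the maximum of 163.35. The input libraries and the read counts behind the peaks were not analysed here, so the depth of each library is unknown and ChIP could not be compared with input beyond the authors' own peak calls.

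Peak lists were compared by overlap of at least 1 bp. Reproducible peaks were defined as nuclear whole-series peaks overlapped by a peak of each replicate. The chance overlap was taken from 100000 random circular rotations of 1 list along each chromosome, which keep the widths and the spacing of the peaks, and p-values from these rotations are one-sided for overlap and two-sided for positions. With 100000 draws the smallest p-value is 1e-05. Chromosome lengths were taken as the last base covered by a peak in any list, because no genome of this build was used here. Peak density was counted from peak centres in equal bins of about 1 Mb, 82 on the 5 autosomes and 18 on X, and compared by a two-sided permutation test over bins (100000 resamples). Neighbouring bins are not independent. Chromosome arms were the outer 25% at each end. Benjamini-Hochberg adjustment was applied within each family of tests. Shares of peaks are given with 95% Wilson intervals, which cover counting error only. With 2 replicates, and with peaks or bins as the units of the tests, p-values describe these lists and not the spread between worm cultures. Nothing in the labels says whether the replicates came from separate cultures.

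The tests were checked on simulated lists in 50 draws each, with the numbers and widths of the peaks of both replicates for the overlap test and of the 4147 reproducible peaks for the arm and X density tests. The overlap test called 50 of 50 draws with planted overlap and 1 of 50 without. The arm test called 50 of 50 draws with planted enrichment and 3 of 50 without. The test of X density called 50 of 50 draws with a planted deficit and 6 of 50 without, more than expected at 0.05. A longer run of 1000 draws without a deficit, added after that count was seen, called 61. Simulated peaks were placed independently and, apart from a planted effect, evenly along and between the chromosomes. The real peaks were clustered and the autosomes differed in density, so the rates of false calls may differ for the real lists. Planted effects smaller than those set here were not examined. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

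The main comparisons, the lists of genes and the alternative settings were fixed before the data were examined, except for the comparisons of X with V alone and with the autosomes without V, which were chosen after seeing the data. Alternatives were the peak set, either replicate alone, the 50% of peaks with the higher scores, an overlap of 50%, merging of neighbouring peaks, equal numbers of peaks, and the sizes of bins and arms. The rule for named items took the 10 reproducible peaks of highest score, ties broken by width, and genes beside them or from the fixed lists. The gene table used here is of another assembly (WBcel235), so no peak was tied to a gene. The shares at promoters, in exons, introns and intergenic sequence, the gene list tests and the GC content were therefore not run, and peaks are named by position only.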

Results

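The data were lists of MRE-11 binding sites in fem-2(b245) young adult hermaphrodites, from 2 ChIP libraries (replicates 1 and 2). The series also has 2 input libraries, which were not analysed here. Replicate 1 had 4212 peaks with a median width of 1265 bp, covering 6.89% of the nuclear chromosomes. Replicate 2 had 5799 narrower peaks, with a median width of 664 bp, covering 5.21%. The whole-series list had 11473 nuclear peaks with a median width of 330 bp, covering 5.68%, and 3 mitochondrial peaks. All positions are in WS220 and are given without gene annotation.

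The first comparison asked how well the MRE-11 sites of one replicate were found again in the other. Most sites were shared: 3325 of the 4212 replicate 1 peaks (78.9%, 95% Wilson interval 77.7% to 80.1%) were overlapped by a replicate 2 peak, and 3868 of the 5799 replicate 2 peaks (66.7%, 65.5% to 67.9%) by a replicate 1 peak. Rotated lists gave 13.6% and 10.9%, so the observed shares were 5.80 and 6.12 times the chance level. Both were above every one of the 100000 rotations (one-sided permutation p = 1e-05, the smallest possible), of which the highest reached 26.5%. The shared bases made up 45.7% of all bases covered by either list, against 3.25% after rotation. The 2 replicates also had similar density landscapes. Across the 100 bins of 1 Mb, their peak densities had a Pearson r of 0.85 and a Spearman rho of 0.85, with r of 0.91 over the 82 autosomal bins and 0.78 over the 18 X bins. Bins within a genome are not independent replicates, so no p-value is given.

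The share of sites found in the other replicate was larger at high scores. In the highest score quintile of replicate 1, all 843 peaks were overlapped by replicate 2 (95% Wilson interval from 99.5%), and in the lowest quintile 456 of 843 were (54.1%, 50.7% to 57.4%). In replicate 2 the share was 44.3% (41.5% to 47.2%) in the lowest quintile and 95.7% (94.4% to 96.7%) in the highest. Among the 3325 overlapping replicate 1 peaks, the scores in the 2 lists had a Spearman rho of 0.65 (95% bootstrap interval 0.62 to 0.67). This is a correlation across peaks, which are not independent replicates.

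**Figure D1:**
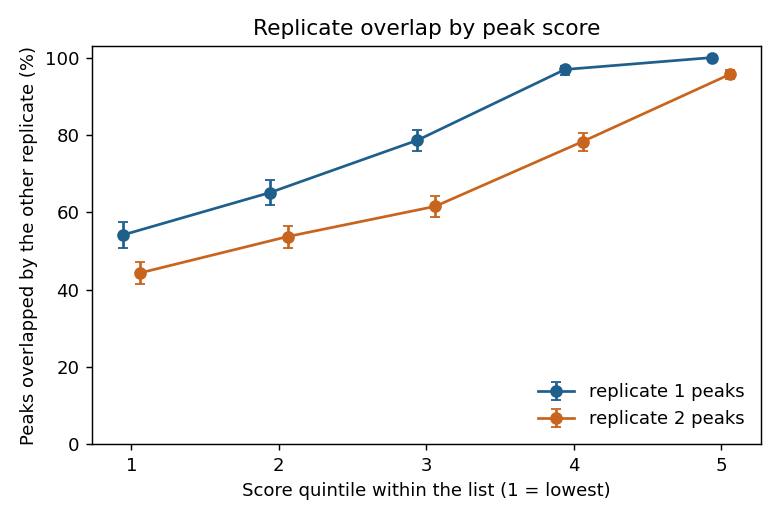
Share of peaks overlapped by the other replicate (y axis, percent) for each score quintile within a list (x axis, 1 is the lowest), for replicate 1 (blue) and replicate 2 (orange), with 95% Wilson intervals as bars. The share rises with score in both lists, from 54.1% to 100% in replicate 1 and from 44.3% to 95.7% in replicate 2.

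The whole-series list was compared with the replicate lists to see which of its sites either replicate had. It contained nearly all replicate peaks: 99.7% of the replicate 1 peaks and 96.9% of the replicate 2 peaks overlapped a whole-series peak. It divided the wide replicate 1 peaks more finely, with 30.1% of them holding more than 1 whole-series peak, against 9.71% in replicate 2. Of its 11473 nuclear peaks, 4147 (36.1%, 35.3% to 37.0%) were in both replicates, 1836 (16.0%) in replicate 1 only, 2052 (17.9%) in replicate 2 only and 3438 (30.0%) in neither. The peaks in neither replicate were weak and narrow, with a median score of 6.03 and a median width of 211.5 bp, whereas the reproducible peaks had a median score of 49.2 and a median width of 617 bp. In the highest score quintile of the whole-series list, 94.9% of the peaks were in both replicates and 1 of 2295 was in neither. All lists came from the same 2 ChIP libraries, so these shares are not independent evidence. Among the 50% of the list with the higher scores, 64.8% of the peaks were in both replicates and 5.81% in neither.

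The reproducible sites of maximum score lay on all 6 chromosomes. There were 172 such peaks in the whole-series list, all of them reproducible, with 45 on IV, 29 on II, 28 on I, 27 on III, 26 on V and 17 on X. Their median width was 1452.5 bp (quartiles 1182.75 and 1885.5 bp). The 10 named here were taken by width among these tied peaks, so their widths do not describe the other sites of that score. The widest was IV 14475952 to 14481139 (5188 bp), found as 5785 bp in replicate 1 and 5125 bp in replicate 2. The next were V 4823605 to 4827570 (3966 bp), III 7178537 to 7182468 (3932 bp), I 11610962 to 11614811 (3850 bp) and III 424421 to 428062 (3642 bp). The remaining peaks of the 10 were IV 15373824 to 15377060, I 2068974 to 2072152, I 534953 to 538061, IV 13880212 to 13883091 and V 9601463 to 9604270, between 2808 and 3237 bp wide. Each of the 10 overlapped a peak with a score of 3100 in both replicate lists.

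MRE-11 sites were unevenly spread over the chromosomes. Reproducible peaks were densest on III, with 62.4 ± 13.8 per Mb (SD over 14 bins), and on I, with 53.3 ± 14.97 per Mb (15 bins). Chromosomes IV and II were intermediate, with 43.0 ± 9.33 (17 bins) and 41.2 ± 12.9 (15 bins). Chromosome V had 29.2 ± 9.66 (21 bins) and X 27.6 ± 8.06 (18 bins). The order of these last chromosomes turned with the replicate: V had 31.3 and X 36.3 peaks per Mb in replicate 1, against 44.02 and 33.0 in replicate 2. Of the 15 pairs of chromosomes, 12 differed in a two-sided permutation test over bins after Benjamini-Hochberg adjustment. The exceptions in these permutation tests were I and III (adjusted p = 0.116), II and IV (adjusted p = 0.648) and V and X (adjusted p = 0.613). The densest bin was III 984552 to 1969103 with 83 reproducible peaks, and the sparsest was X 6890680 to 7875061 with 13. Within chromosomes the peaks were clustered: the variance of the bin counts was 3.16 times their mean, against 1.00 for peaks placed at random (1000 draws, one-sided permutation p = 9.99e-04, the smallest possible). The longest stretch without a reproducible peak was V 2731047 to 3204369 (473323 bp).

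**Figure D2:**
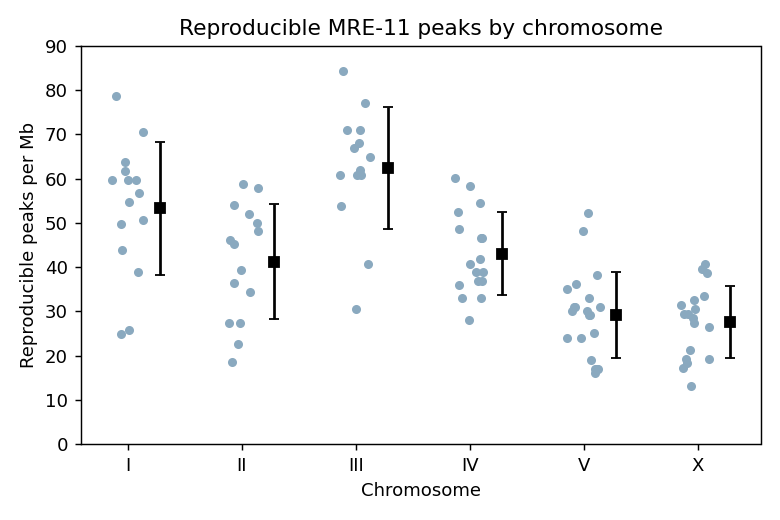
Reproducible peaks per Mb (y axis) in each bin of about 1 Mb (grey-blue points) for the 6 chromosomes (x axis), with the mean and SD over bins as black squares and bars. Chromosomes III and I have the highest means (62.4 and 53.3), and V and X the lowest (29.2 and 27.6).

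The sex chromosome was compared with the autosomes because X and autosomes differ in chromatin state in the worm germline. The ground worms also hold somatic nuclei, so the peaks are not those of the germline alone. X had fewer reproducible MRE-11 peaks, 27.6 ± 8.06 per Mb (SD over 18 bins) against 44.4 ± 16.5 (82 autosomal bins), a difference of -16.76 per Mb and an autosomal density 1.61 times that of X (two-sided permutation p = 8e-05). This test shuffles bins as interchangeable and leaves out differences between whole chromosomes. The autosome means themselves ran from 29.2 on V to 62.4 on III, and there is only 1 X. The p-value therefore does not show a deficit particular to X. The size of the gap between X and the autosomes depended on the replicate. In replicate 2 the autosomes had 63.2 ± 20.8 peaks per Mb and X 33.0 ± 9.12 (difference -30.26 per Mb, p = 1e-05, two-sided permutation test). In replicate 1 they had 43.3 ± 13.6 and 36.3 ± 9.98 (difference -6.91 per Mb, permutation p = 0.0452). Against chromosome V alone, a comparison chosen after seeing the data, the difference was -1.65 per Mb and did not pass the test (permutation p = 0.572).

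The replicates differed in which chromosomes their unshared sites came from. Replicate 2 had more peaks than replicate 1 on each autosome, from 1.41 times as many on V to 1.58 times on I, and fewer on X, at 0.91 times. Of the replicate 1 peaks, 66.3% on X (62.6% to 69.8%, n = 644) and 81.2% on the autosomes (79.9% to 82.5%, n = 3568) were overlapped by replicate 2, which differed by Fisher's exact test (two-sided p = 3.25e-16). Of the replicate 2 peaks the order was the other way, with 82.9% on X (79.6% to 85.7%, n = 584) and 64.9% on the autosomes (63.6% to 66.2%, n = 5215; Fisher's exact two-sided p = 4.63e-20). These tests treat peaks as independent, and neighbouring peaks are not. The 2 opposite contrasts also follow in part from the numbers of peaks that each list has on X and on the autosomes. They are therefore not separate evidence. Peaks covered 5.59% of X in replicate 1 and 2.71% in replicate 2, a ratio of 0.49, whereas the same ratio on the autosomes lay between 0.76 on V and 0.87 on I.

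**Figure D3:**
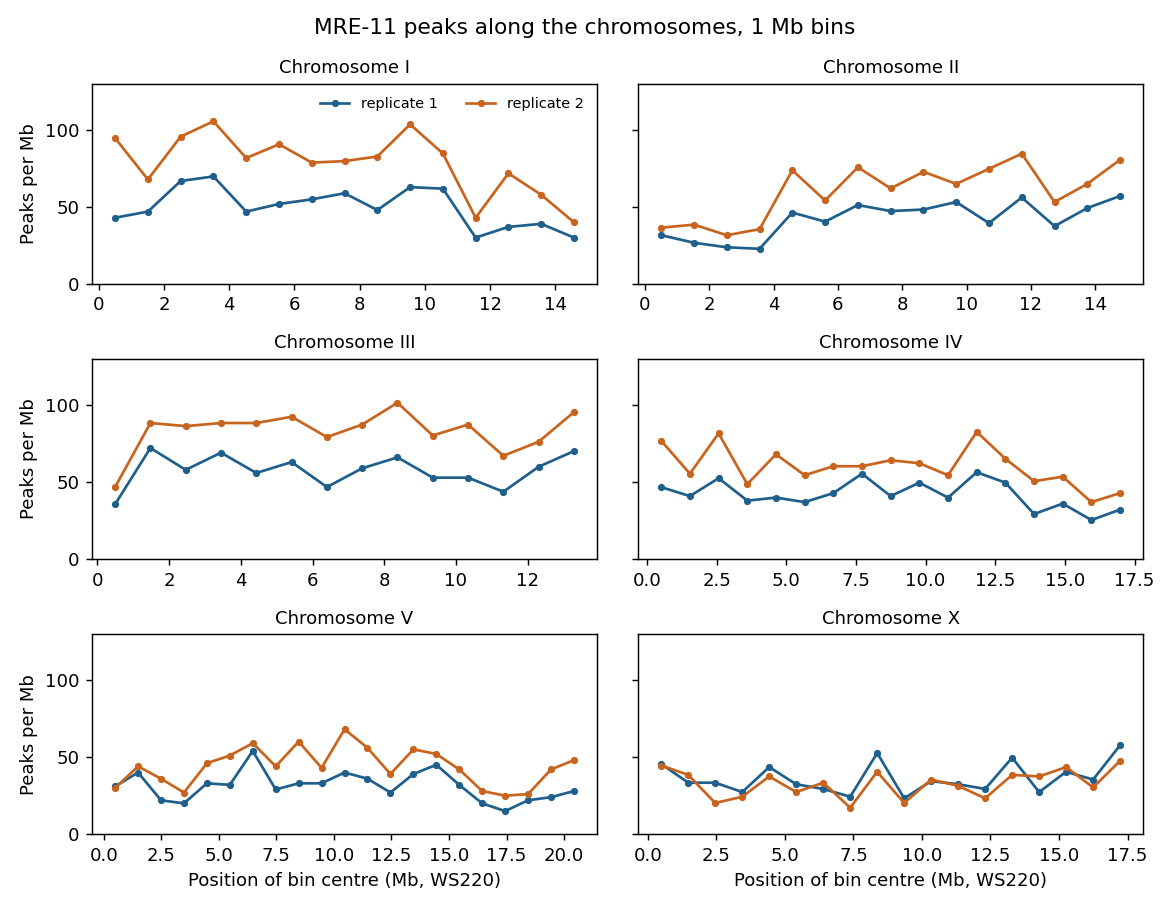
Peaks per Mb (y axis) in bins of about 1 Mb along each chromosome (x axis, Mb in WS220) for replicate 1 (blue) and replicate 2 (orange). Replicate 2 lies above replicate 1 along most of the autosomes, whereas on X the 2 lines run close together, with means of 33.0 in replicate 2 and 36.3 in replicate 1.

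Chromosome arms were compared with centres because meiotic crossovers in C. elegans occur mostly on the arms and MRE-11 acts on meiotic breaks. The peaks came from ground worms, which hold somatic as well as germline nuclei, and were not tied to meiotic breaks. On the autosomes 1693 of 3658 reproducible peaks (46.3%, 44.7% to 47.9%) lay in the outer 25% at each end, against 49.99% ± 2.07 (SD) after rotation, and the difference did not pass the test (two-sided permutation p = 0.0725). The lowest arm share was that of V, 40.4% (36.5% to 44.3%), and the highest among autosomes that of III, 49.8%. On X 54.6% (50.2% to 59.0%) of the peaks lay in the arms. No chromosome of the 6 passed the rotation test after adjustment (lowest unadjusted permutation p = 0.0634, on V). The arm share of X was 8.32 percentage points above that of the autosomes, which did not pass (permutation p = 0.201), although it did with the lists of replicate 1 (8.34 points, p = 0.00974) and replicate 2 (10.3 points, p = 0.0161) and with every whole-series peak (4.74 points, p = 0.0308, two-sided permutation tests). With either replicate's own list the autosomal arm share passed the test, with 2347 of 5215 peaks in replicate 2 (p = 0.00414) and 1625 of 3568 in replicate 1 (45.5%, p = 0.00972), and with the whole-series list it was 45.9% (p = 0.0301, two-sided permutation tests).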

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

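Mitochondrial peaks lay outside the comparisons of nuclear chromosomes. The whole-series list held 3 of them, from 1 to 10567 (score 34.65), from 10700 to 13299 (score 29.88) and from 13498 to 13796 (score 7.77), together covering 97.6% of the mitochondrial sequence, while the replicate lists held 0, although 99.9% of nuclear whole-series peaks with a score of at least 29.88 were in a replicate list.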

How the results depend on the processing

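Both replicate overlaps kept their direction and their side of the threshold under all of the alternatives run, but their size moved. With an overlap of 50% the shares were 61.5% of replicate 1 and 65.4% of replicate 2 peaks, 14.4 and 9.04 times rotation. With equal numbers of top-scoring peaks they were 66.9% and 74.3%, 6.15 and 6.47 times rotation. X density and arm share also kept their direction in all alternatives. Score ranks and whole-series shares were not set against a chance level, so only their size was followed. Some orders did turn. In both of these overlap settings the share was larger in replicate 2 than in replicate 1, the other way from the main setting. Among the higher-scoring 50% of the whole-series list, peaks in neither replicate became fewer than those in either replicate only. The order of V and X by density also turned with the replicate. With an overlap of 50% the rank correlation of the scores was 0.70, the share of the highest quintile of replicate 1 was 89.3% and that of the lowest 44.4%, and 34.9% of the whole-series peaks were in both replicates. The replicate 1 peaks are the wider ones, so this rule asks more of them. In the 50% of the whole-series list with the higher scores the shares were 64.8% in both replicates, 13.5% in replicate 1 only, 15.8% in replicate 2 only and 5.81% in neither. The lower density of X passed the test over bins, which leaves out differences between whole chromosomes, in all alternatives fixed beforehand. Leaving out 1 replicate gave differences from -30.26 (replicate 2 alone) to -6.91 per Mb (replicate 1 alone). In 2 comparisons chosen after seeing the data, it was -21.96 per Mb without V and -1.65 against V alone, where it no longer passed. The autosomal arm share was below rotation in all alternatives. It passed the threshold with every whole-series peak (45.9%) and when leaving out 1 replicate (45.005% to 45.5%), and not with the 50% of peaks with the higher scores, an overlap of 50%, or arms of 33.3% or 10% (p from 0.0697 to 0.385, two-sided permutation tests); the cause was not tested. Promoter share, gene list enrichment and GC content were not run under any setting, since no genome or annotation of this build was used here. Read depth is unknown, so whether peaks found in 1 replicate lacked signal in the other or lacked reads is open. No paired analysis was possible because the input libraries that share replicate numbers with the ChIP libraries have no values among the lists.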

Other observations

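All tests in this part were chosen after the results were seen, except the comparison of the 2000 highest-scoring peaks and that of 50 kb windows, whose outcomes were predicted before they were computed.

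None of the 10 widest reproducible peaks had the maximum score. The widest, I 15060227 to 15071352 (11126 bp, score 36.12), lay at the right end of chromosome I, where the tandem genes of the large ribosomal RNA precursor are known to be. It was 11833 bp wide in replicate 1 and 11258 bp in replicate 2. Input was not analysed here, so occupancy by MRE-11 at these tandem genes could not be separated from the number of gene copies. The next were X 16929325 to 16940143 (10819 bp, score 131.90) and V 7915532 to 7925034 (9503 bp, score 127.05), both at a score of 3100 in each replicate list. The peak at V 17119930 to 17126579 (6650 bp) was 12957 bp wide in replicate 1 and 7040 bp in replicate 2. The spacing of sites also differed: the median gap between reproducible peaks was 5525 bp on III and 18040 bp on X.

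The smaller share of X in replicate 2 was not removed by ranking. X held 15.3% of the peaks of replicate 1 and 10.1% of those of replicate 2, and among the 2000 highest-scoring peaks of each list it held 280 and 155 peaks, a difference of 6.25 percentage points (95% interval 4.33 to 8.17). A larger number of weak calls in replicate 2 would have brought these shares together. The 95% intervals given here treat peaks as independent, which neighbouring peaks are not, and cover counting error only. On the whole-series peaks as common units, the odds of being in replicate 1 only against replicate 2 only were higher on X. They were 4.70 times those on the autosomes (95% interval 3.73 to 5.90). This argues against the merging of neighbours within wide replicate 1 peaks as the whole cause. With peaks within 2000 bp merged in each list, the difference in X share was 4.28 percentage points (95% interval 2.70 to 5.85). It was 5.22 points over all peaks, so merging may carry a part of it. A difference between the replicates in tissue makeup, in their input libraries or in sequencing remains open; the labels name no batch for either library, and no biological explanation was tested.

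Reproducible peaks were fewer on the chromosome arm that carries the meiotic pairing centre, taken from textbook knowledge as the right end of I, IV and V and the left end of II, III and X. The arm without the centre had more peaks on 6 of 6 chromosomes, from 216 against 212 on III to 197 against 91 on II, with a mean log2 ratio of -0.48 ± 0.17 (SE over chromosomes; exact two-sided sign-flip p = 0.03125, the smallest possible with 6 chromosomes and not corrected for the choice of the pattern). Without II the mean was -0.35, and counting each 50 kb window once it was -0.18 ± 0.09 (-0.10 without II), below 0 on 5 of 6 chromosomes and tied on III (60 windows on each arm). This was below 0 by more than its SE, as it was without any 1 chromosome. The exact two-sided sign-flip test of the windows did not pass (p = 0.0625, which the tie on III keeps from being lower). The windows thus argue only weakly against a few dense clusters as the whole cause. The ratio on I went from -0.86 in peaks to -0.08 in windows. The window means were -0.12 in replicate 1, -0.13 in replicate 2 and -0.02 over every whole-series peak. An arm has a limited number of windows, and whole-series peaks filled most of them, such as 74 on each arm of I. This draws window ratios toward 0 whether or not peaks cluster, so the part that clusters carry cannot be told. Weak whole-series peaks found in neither replicate had a mean of -0.35 ± 0.10 in the same direction. A property of these arms that lowers peak calls in general would give this. Repeats that take few unique reads or closed chromatin are candidates for it. These weak peaks came from the same ChIP libraries and may include weak MRE-11 sites. Sparser MRE-11 would therefore give the same direction, and this value cannot separate the 2 explanations. Repeats and chromatin were not examined, and a hypothesis that MRE-11 itself is sparser on these arms stays untested.

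Each of the 6 chromosomes had a peak that began at base 1 in both replicate lists and in the whole-series list, where rotation gave 0.42, 0.32 and 0.35 chromosomes on average and at most 5 (one-sided permutation p = 1e-05 for each list, the smallest possible). The end peaks were 601 to 1513 bp wide in replicate 1 and 350 to 1139 bp in replicate 2. Their scores ranged from percentile 26.9 to 82.6 of the replicate 1 list and from 45.3 to 79.3 of the replicate 2 list, with medians of 62.2 and 62.5. These medians are not low, but the ends of IV in replicate 1 (26.9) and III in replicate 2 (45.3) ranked under 50, and the end of IV was at 51.1 in replicate 2, so whether some of the calls are effects of the edge is left open. Telomere repeats, whose reads do not map uniquely, are a candidate source that was not tested, beside the hypothesis that MRE-11, which acts at telomeres in other organisms, occupied these ends. At the right ends the last peak of the replicate lists stopped between 721 and 53511 bp before the last base of the whole-series list. That base also set the chromosome length used here, so the whole-series list reaches it by definition. The replicate lists thus had a peak at the left end of each of the 6 chromosomes and at no right end. Neither candidate source was tested against this difference between the ends. The one peak of the highest whole-series score quintile that was in neither replicate was the last of X, from 17718249 to 17718889 (score 84.63).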
